A study of Mus musculus with 31 samples.

How the data were processed

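DNA double-strand breaks of meiosis were mapped in mouse testis by DMC1 SSDS, which recovers and sequences the single-stranded DNA bound by the recombinase DMC1 at resected break ends. The labels give 31 samples: 26 DMC1 libraries, 1 for each of 26 genotypes, and 5 input samples that carry no hotspot list and were not used here. Each library was grouped by the strain of its mother and of its father as the labels state them. The series text says that a sample was removed because it was wrongly labelled as a cross of a CAST mother and a 13R father, and the sample it points to is labelled CAST here; values for CAST assume that this label is right. The CAST list shared 0.599% of the shorter list with 13R, and the 5 crosses with a CAST parent recovered 97.6% to 98.4% of its strongest 5000 hotspots. The 26 lists comprise 6 inbred strains, 19 F1 crosses and 1 Prdm9 knockout. With 1 library per genotype there are no replicates, so a difference between any 2 lists has no replicate check, and tests compare sets of lists. Crosses that share a parent are not independent, and permutation p-values over crosses treat them as if they were.

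Each file is a list of hotspots called in 1 library by the authors, with a chromosome, a start, an end and a strength score per hotspot. Per the submitters' processing notes, the build was mm10 and the tools included CASAVA 1.8 and MACS2 2.0.10. The filters and the normalization of the deposited score, and whether animals were pooled, are not given in the sources used here. The deposited strength score has 3 decimals, and 104 of the 414683 values, in 22 of the 26 lists, lie below 0. The score was therefore used only within a list, as a share of the summed strength, a rank or a percentile. The exceptions are a place near Gm2244 and a hotspot at Tollip, for which raw scores are printed that are not comparable between lists. The read depth of the libraries is unknown, so list lengths are not read as numbers of breaks. Exact Clopper-Pearson intervals at the 95% level were computed for shares of hotspots, and they cover counting error only.

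A hotspot was counted as shared when the centres of hotspots in both lists lay less than 400 bp apart, on the 19 autosomes unless X or Y is named. The chance level came from 100 circular shifts of 1 list along each chromosome, by at least 5% of its span. Coordinates are printed 1-based. Genes were taken from a RefSeq gene table of GRCm38.p6, the same primary assembly as mm10, which placed 21883 protein-coding genes. It gives the start and end of a gene but not its strand, so the planned promoter tests were run on gene ends: a hotspot was near a gene end when its centre lay within 1000 bp of either end of a protein-coding gene. Either end can be the transcription start. The planned search for sequence motifs at hotspot centres was not run, because a genome sequence was not used here. The plan took chromosome lengths from a reference; instead, chromosome length was taken as the larger of the last hotspot end and the last gene end.

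For each F1 cross, hotspots were divided into those at a hotspot of the mother's strain, of the father's strain, of both, at a knockout site alone, and at none of these, called neither parent. The planned tests were a two-sided exact permutation test of knockout-site shares between crosses with a PWD parent (6) and other crosses (13), a permutation test of X shares between inbred and F1 lists with 100000 resamples, a permutation of list labels for the similarity of reciprocal crosses with 100000 resamples, and two-sided exact or 100000-resample sign-flip permutation tests over reciprocal pairs or crosses. The plan did not state the side of the reciprocal test, which was run one-sided. Fisher's exact test compared the knockout list with the B6 list at gene ends, which compares those libraries only, and tested 7 gene lists with Benjamini-Hochberg adjustment over the 7. The gene lists covered meiotic prophase, spermatids, spermatogonia, Sertoli cells, Leydig cells, ribosomal proteins and olfactory receptors. The threshold was 0.05.

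The tests, the gene lists, the alternatives and the rule for named hotspots were written before the data were examined, apart from the departures named above. The rule named the strongest autosomal hotspot of each inbred list, the 10 strongest of the knockout list, the strongest hotspot in neither parent of each cross with B6, hotspots present in all 6 inbred lists, hotspots within 10000 bp of Psmb9, H2-Eb1, Hlx and Esrrg, and up to 4 members of each gene list. One hotspot that the rule names, in 13RfXB6m, is not reported here. A named gene is the gene whose span holds the hotspot centre, otherwise the protein-coding gene with the nearest end. The medians used as summaries, the naming of the inbred pairs with high sharing, and the division of crosses into those among B6, C3H and 13R and those with a CAST, MOL or PWD parent were chosen after seeing the data. The alternatives covered other overlap rules, stronger subsets of each list, other windows at gene ends and shares by strength. Leaving out each list in turn was added after seeing the data.

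The matching and the classes of origin were tested on simulated data made from the real lists. In 7 simulated shares, the recovered share differed from the true one by at most 0.805 percentage points. The largest error was at a true share of 1.09% that was recovered as 1.90% because chance matches add to it. The simulated shared centres were moved by less than the 400 bp of the matching rule, so true matches could not be missed. The check therefore covers chance matches and says nothing on matches that the rule misses in the real lists. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.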

Results

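Meiotic double-strand breaks were mapped in testis of 26 mouse genotypes to compare where recombination starts in different strains and in their hybrids. The inbred strains were B6 (C57Bl/6J), C3H (C3H/HeJ), 13R (B10.F-H2pb1/(13R)J), CAST (CAST/EiJ), MOL (MOLF/EiJ) and PWD (PWD/PhJ). Crosses are named by mother (f) and father (m), so PWDfXB6m had a PWD mother and a B6 father. The Prdm9 knockout lacks PRDM9, the zinc-finger histone methyltransferase whose DNA binding places most hotspots in mice and which differs between strains. The 26 lists held 414683 hotspots, and each genotype had 1 library, so no value below has a replicate error.

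The 6 inbred lists held between 14539 hotspots, in PWD, and 19528, in B6, with a median of 14910. The 19 F1 lists ranged from 10445 in B6fX13Rm to 19084 in PWDfXCASTm, with a median of 15858. The knockout list was the longest, with 30929 hotspots. Median hotspot width lay between 1745 and 2258 bp in the inbred lists and between 1622 and 2110 bp in the F1 lists, and was 2098 bp in the knockout. The strongest 10% of hotspots held 32.2% of summed strength in 13R, 41.3% in B6, 46.2% in PWDfXB6m and 32.3% in the knockout.

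The strongest autosomal hotspot of each inbred strain lay at a different place. In B6 it lay inside Gabrb1, a GABA receptor subunit gene, on chromosome 5 (71870110 to 71874145). In C3H it lay inside Epc1 on chromosome 18 (6437363 to 6445038), and in PWD inside Klf5, a transcription factor gene, on chromosome 14 (99306091 to 99310216). The strongest in 13R lay at chromosome 10 (88471976 to 88473781), centred 358 bp from an end of Sycp3, which encodes a lateral element protein of the synaptonemal complex. In CAST it lay 23279 bp from Tpd52 on chromosome 3 (9026456 to 9030889), and in MOL 127374 bp from Mex3c on chromosome 18 (73443146 to 73447381). Stronger hotspots lay off the autosomes in all of these lists: the named hotspots ranked 34 in B6, 28 in C3H, 3 in 13R, 7 in CAST, 27 in MOL and 40 in PWD.

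Most pairs of inbred strains had almost no hotspots in common. Of the 15 pairs, 4 stood well above the rest. B6 and C3H shared 33.3% of the shorter list (95% Clopper-Pearson interval 32.5 to 34.1, 4575 of 13742), which was 54.7 times the mean of the shifted lists. PWD shared 13.0% of its hotspots with MOL (12.4 to 13.5) and 11.9% with CAST (11.3 to 12.4), 26.3 and 25.4 times chance. CAST and MOL shared 2.66% (2.40 to 2.94), 5.60 times chance. Among the strongest 5000 hotspots of each list these shares fell to 17.0% for B6 and C3H, 6.58% for MOL and PWD, 7.87% for CAST and PWD and 1.08% for CAST and MOL, so that PWD shared more with CAST than with MOL, as also in the strongest 50% (9.69% against 8.63%). CAST and MOL shared 1.56% in the strongest 50% and 5.55% with any overlap of the intervals. The lowest share, 0.599% between 13R and CAST, lay within the range of the shifted lists, where the highest was 0.657%, and the median over the 15 pairs was 0.833%. In 14 pairs the share exceeded all 100 shifted lists, and in 10 it also exceeded all shifts of 20 to 100 kb, which keep the regional density of hotspots. No autosomal hotspot of B6 was present in all 6 inbred lists, so the rule for such hotspots named none; the shifted lists gave 0 as well.

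**Figure D1:**
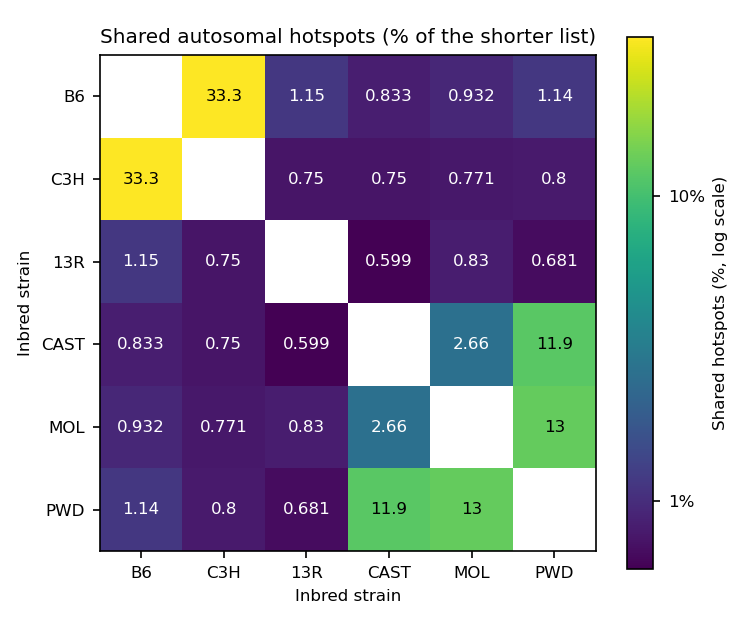
Shared autosomal hotspots for each pair of the 6 inbred strains, as a percentage of the shorter list; both axes are strains and colour follows a log scale. B6 and C3H reach 33.3%, PWD shares 13.0% with MOL and 11.9% with CAST, and 13R shares at most 1.15% with any strain.

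To ask which parent sets the hotspots of a hybrid, each F1 hotspot was matched to both parental lists. In the 5 crosses among B6, C3H and 13R, between 1.60% (B6fX13Rm) and 5.91% (C3HfX13Rm) of hotspots lay in neither parent, with a median of 3.19%. In the 14 crosses with a CAST, MOL or PWD parent the share was between 16.8% (MOLfX13Rm) and 29.7% (B6fXPWDm), with a median of 21.9%. These hotspots held 1.58% to 4.75% of summed strength in the 5 crosses and 16.7% to 36.1% in the 14. The ranges did not overlap, but the division was made after seeing the data and was not tested. The values themselves depended on the matching rule, and the median over all crosses, 20.7%, rose to 37.1% when only the strongest 5000 hotspots of each list were compared.

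**Figure D2:**
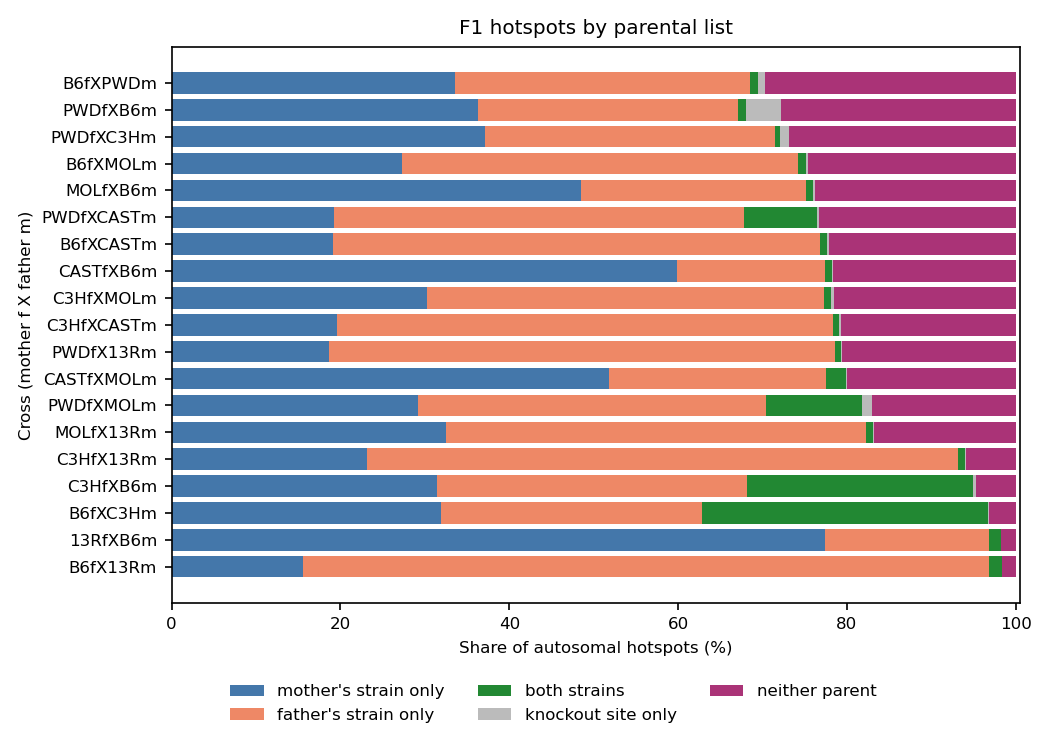
Share of autosomal hotspots (%, horizontal axis) in each of 19 F1 crosses (vertical axis) that lay at a hotspot of the mother's strain only, the father's strain only, both, a knockout site only or neither parent. Crosses are ordered by the share in neither parent, which runs from 1.60% in B6fX13Rm to 29.7% in B6fXPWDm.

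The parents did not contribute equally. Among autosomal hotspots found in only 1 parental list, 13R supplied 79.9% in 13RfXB6m (79.2 to 80.7) and 83.9% in B6fX13Rm (83.1 to 84.6), 75.2% against C3H, 76.3% against PWD and 60.5% against MOL. CAST supplied 75.1% in B6fXCASTm and 77.3% in CASTfXB6m, 75.0% against C3H, 71.6% against PWD and 66.8% against MOL. MOL supplied 63.3% in B6fXMOLm and 64.5% in MOLfXB6m, 60.9% against C3H and 58.6% against PWD. Against B6 and C3H, PWD was near parity: PWD supplied 51.0% in B6fXPWDm, 54.0% in PWDfXB6m and 52.0% in PWDfXC3Hm. In C3HfXB6m, C3H supplied 46.2% of such hotspots but 53.7% of their strength. The shares depend on list length, since B6 offered 18130 autosomal hotspots and 13R 13850. Taking the strongest 5000 hotspots of each parent evens out the parental numbers, but recovery can still depend on the length of the cross list. B6fX13Rm (10445 hotspots) recovered 99.4% of those of 13R and 33.3% of those of B6, and 13RfXB6m (13361) 99.5% and 50.1%. CASTfXB6m recovered 98.4% of CAST and 35.3% of B6, and B6fXCASTm 98.0% and 38.2%. PWDfXB6m (17518) recovered 84.3% of PWD and 74.6% of B6, and B6fXPWDm (13606) 69.4% and 63.7%.

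The strongest autosomal hotspots in neither parent were named for crosses with B6. In B6fX13Rm it lay at Tollip on chromosome 7 (141880062 to 141883529), 215 bp from a gene end. Both directions of the B6 and C3H cross had it inside Met, the hepatocyte growth factor receptor gene, on chromosome 6 (17526180 to 17530583 in B6fXC3Hm). B6fXPWDm had it 1024 bp from an end of Gfra1, a GDNF receptor gene, on chromosome 19 (58232722 to 58236393), and PWDfXB6m inside Pdlim1 on chromosome 19 (40220636 to 40225637). B6fXMOLm had it 58466 bp from Prdm9 itself on chromosome 17 (15620863 to 15624818). In both B6 and CAST crosses and in MOLfXB6m it was the same place on chromosome 14, near Gm2244, from 19416511 to 19419940 in B6fXCASTm. Its strength of 7852 there compared with 349 for the next autosomal hotspot, and it counts in the 29.2% of strength in neither parent of that cross. Whether so strong a signal at this place reflects breaks was not tested. The hotspot at Tollip also stood apart within B6fX13Rm, at rank 1 with a strength of 1550 against 437 for the next autosomal hotspot. Whether that signal reflects breaks was not tested either.

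Hotspots in neither parent were not weaker or stronger than parental ones by a margin larger than the spread between crosses. Their median strength percentile averaged 46.3 against 49.8 for parental hotspots, a difference of -3.57 ± 12.1 (SD, n = 19), with higher values in 9 crosses (two-sided sign-flip permutation test, p = 0.218). The difference was -20.8 ± 6.34 in the crosses among B6, C3H and 13R, where it was negative in all 5; the exact permutation p of 0.0625 is the smallest that 5 crosses allow. In the other crosses it was 2.59 ± 5.92 (n = 14, permutation p = 0.124). With reciprocal overlap of at least 50% as the matching rule, the difference over 19 crosses was -18.0 (permutation p = 2.0e-05). Under the other alternatives it lay between -2.45 and -0.876 and did not pass.

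In crosses made in both directions, nearly all hotspots of the shorter list were found in the longer one. The lists held 9748 and 12448 autosomal hotspots for 13R, 12850 and 17123 for C3H, 11968 and 15247 for MOL, and 12918 and 16759 for PWD. In these pairs the longer list therefore held many hotspots not found in the shorter, while the CAST lists were near equal (14383 and 14609). The 5 reciprocal pairs with B6 shared between 94.4% (CAST) and 99.0% (C3H) of the shorter list, and Spearman's rho of strength across shared hotspots was between 0.925 (PWD) and 0.957 (CAST); hotspots are not independent replicates. The mean share was 97.5% ± 1.86 (SD, n = 5) for reciprocal pairs, 36.8% ± 18.5 for the 100 pairs of crosses with 1 parent in common and 6.54% ± 5.70 for the 66 pairs with none. The first exceeded the second by 60.7 percentage points (one-sided permutation of list labels, p = 1e-05, the smallest that 100000 resamples give). Pairs of lists that share a library are not independent.

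The parental balance moved in both directions when the cross was turned around. With B6 as mother rather than father, the B6 part of single-parent autosomal hotspots was lower by 3.92 percentage points with 13R and 2.94 with C3H, and higher by 2.19 with CAST, 1.22 with MOL and 2.97 with PWD. The mean difference was -0.0971 on the autosomes (exact sign-flip permutation p = 1) and -1.33 on X (higher in 1 of 5 pairs, exact permutation p = 0.188). The smallest p that 5 pairs allow is 0.0625, so the test could not pass and does not settle whether direction matters. The autosomal sign turned under 3 alternatives, to 1.79, 0.399 and 1.30 percentage points. With 13R and C3H the B6-mother list was the shorter (9748 against 12448 and 12850 against 17123 autosomal hotspots). Single-parent hotspots of B6 were also the weaker there, at a median percentile of 29.1 against 53.9 in B6fX13Rm and 37.6 against 48.3 in B6fXC3Hm. In those pairs cross direction cannot be told apart from a longer list reaching weaker hotspots.

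In the knockout, breaks form at sites that do not depend on PRDM9, and the question was how far other genotypes use these sites. PWDfXB6m stood apart: 5.93% of its autosomal hotspots lay at knockout sites (5.57 to 6.29, 993 of 16759), against a mean of 1.00% for shifted lists. PWDfXMOLm followed with 2.40% (2.16 to 2.66), the reciprocal cross B6fXPWDm with 2.14% (1.90 to 2.41) and PWDfXC3Hm with 2.13% (1.91 to 2.37). These shares include sites that are also hotspots of a parent. At knockout sites alone lay 4.13% in PWDfXB6m, 1.15% in PWDfXMOLm, 0.774% in B6fXPWDm and 1.05% in PWDfXC3Hm. The crosses of PWD with CAST (0.744%) and 13R (0.633%) lay below the shifted lists. Among inbred strains, PWD had 1.76% and B6 1.58%, while 13R had 0.700%. The hotspots concerned were weak, and held 2.04% of summed strength in PWDfXB6m. The share in that cross ran from 11.8% with any overlap of the intervals to 0.667% in the strongest 50% of each list and 0.168% in the strongest 5000. Of the autosomal hotspots among the strongest 1000 of the knockout, 47.3% were found in that cross, against 15.7% in PWDfXMOLm, 15.6% in PWDfXC3Hm, 11.4% in B6fXPWDm, 10.2% in PWD and 9.73% in B6.

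The mean share at knockout sites was 2.33% ± 1.92 (SD, n = 6) in crosses with a PWD parent and 0.962% ± 0.275 (n = 13) in other crosses, a difference of 1.37 percentage points (two-sided exact permutation test, p = 0.00604). One library carried much of it: without PWDfXB6m the difference was 0.649 (exact permutation p = 0.0191), and without both crosses between B6 and PWD it was 0.516 (p = 0.0580 by exact permutation, n = 4 against 13). With reciprocal overlap of at least 50% it was 0.457 (exact permutation p = 0.0263), by summed strength 0.386 (exact permutation p = 0.0109), and in the strongest 50% of each list 0.0684 (exact permutation p = 0.237).

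**Figure D3:**
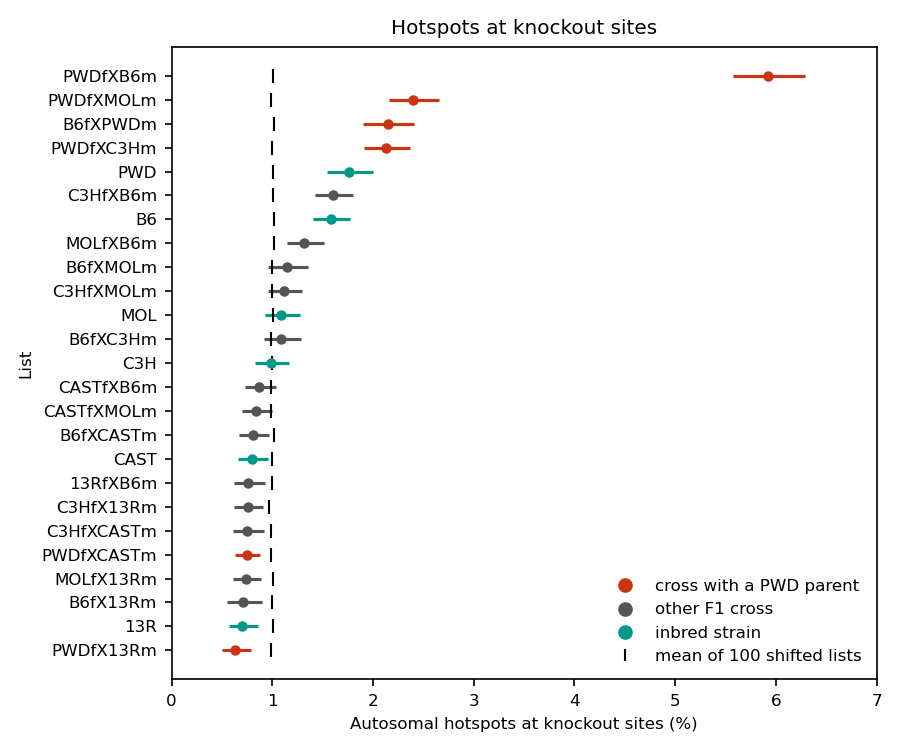
Share of autosomal hotspots at knockout sites (%, horizontal axis) in the 25 lists other than the knockout (vertical axis); points are shares, bars are 95% Clopper-Pearson intervals and black ticks are means of 100 shifted lists. PWDfXB6m lies at 5.93% and all other lists lie between 0.633% and 2.40%.

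Knockout hotspots gathered at gene ends. Of the 30929 knockout hotspots, 33.5% (32.9 to 34.0) had their centre within 1000 bp of an end of a protein-coding gene, against 3.89% in B6 (3.62 to 4.17) and 3.05% in shifted knockout lists. Among the strongest 5000 the shares were 66.4% and 2.68%. The odds ratio of knockout against B6 was 12.4, and Fisher's exact p was too small for the software to represent; the test compares these libraries only. The strongest autosomal knockout hotspots included one inside Muc3, a mucin gene, on chromosome 5 (137151908 to 137154803, rank 1), one inside Enpp6 on chromosome 8 (rank 2), one inside Zkscan16 on chromosome 4 (rank 3), and ones in Rsbn1l, St7 and Snx13. Others were centred 27 bp from an end of Cenpl, which encodes a centromere protein, 186 bp from Nudcd2, 147 bp from Kbtbd8 and 16411 bp from Chd2, a chromatin remodeller gene.

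Genes of meiosis and ribosomal protein genes had knockout hotspots at their ends more often than other protein-coding genes, and olfactory receptor genes far less often. Of 48 meiotic prophase genes, 41 had one (85.4%, 72.2 to 93.9), against 50.9% of other genes (Fisher's exact test with Benjamini-Hochberg adjustment over 7 lists, adjusted p = 1.74e-06). The strongest were at Mybl1, a transcription factor of male meiosis (rank 19), Syce1 of the synaptonemal complex (rank 332), Terb1, which tethers telomeres to the nuclear envelope (rank 381), and the cohesin gene Rad21l (rank 694). Of 80 ribosomal protein genes 64 had one (80%, Fisher's exact test, adjusted p = 3.98e-07), with Rps13 at rank 252 and Rps27a at rank 751. Only 26 of 1110 olfactory receptor genes had one (2.34%, exact test, adjusted p = 1.20e-302), the strongest at Olfr281 (rank 4204). Spermatid genes (10 of 32, 31.3%, exact test, adjusted p = 0.0455; Catsper2 rank 1056, Spaca1 rank 4647) and Leydig cell genes (1 of 9, 11.1%, adjusted p = 0.0337; Cyp11a1 rank 24237) had fewer, and both calls were lost with a window of 2500 bp, at adjusted p = 0.0583 and 0.0570. Spermatogonial genes (13 of 18, 72.2%, exact test, adjusted p = 0.113; Sohlh2 rank 554, Ddx4 rank 1160) and Sertoli cell genes (7 of 19, 36.8%, adjusted p = 0.255; Vim rank 12684) did not pass. In the B6 list, meiotic prophase genes did not pass the same exact test (4 of 48, 8.33%, against 3.71% of other genes, adjusted p = 0.360), and olfactory receptor genes were again low (11 of 1110, 0.991% against 3.87%, adjusted p = 9.24e-08).

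The X chromosome, present once in males and inherited from the mother, held a smaller part of the hotspots in hybrids on average, but not in all of them. The X share was 6.19% ± 0.603 (SD, n = 6) in inbred lists and 5.15% ± 0.848 (n = 19) in F1 lists, a difference of 1.03 percentage points (two-sided permutation test, p = 0.0111). By summed strength it was 11.8% ± 1.22 (n = 6) against 8.84% ± 2.51 (n = 19, permutation p = 0.0107). The 5 crosses among B6, C3H and 13R held 11.8% ± 1.5004 of strength on X, like the inbred lists, and by number 13RfXB6m (6.74%) and B6fX13Rm (6.59%) lay above the inbred mean. The lowest strength shares were 5.20% in B6fXPWDm and 5.72% in PWDfXB6m, and the highest was 13.9% in inbred PWD. The knockout had 3.02% of hotspots (2.83 to 3.22) and 4.30% of strength on X. Crosses with a PWD parent (n = 6) lay below other crosses (n = 13) in X share by a margin that did not pass: 5.00% ± 0.592 against 5.22% ± 0.956 of hotspots (exact permutation p = 0.598), 7.47% ± 1.91 against 9.48% ± 2.56 of strength (exact permutation p = 0.106), and 5.37% ± 0.879 against 6.53% ± 1.52 of the strongest 5000 hotspots (exact permutation p = 0.103). No list had a hotspot in the pseudoautosomal region. The filters behind the lists are not given, so this cannot be read as an absence of breaks there.

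**Figure D4:**
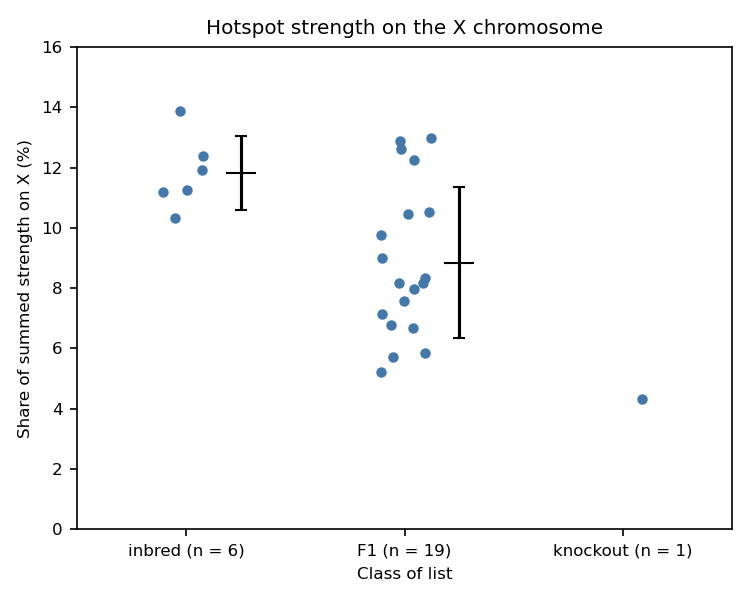
Share of summed hotspot strength on X (%, vertical axis) by class of list; each point is 1 list, and the horizontal marks and bars are the mean and SD of inbred (n = 6) and F1 (n = 19) lists. Inbred lists lie between 10.3% and 13.9%, F1 lists reach down to 5.20%, and the knockout lies at 4.30%.

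At 4 loci known as recombination hotspots in mice, the hotspots of CAST near Psmb9, Hlx and H2-Eb1 were seen in all 5 crosses with a CAST parent. Hotspots of B6 and 13R there were not found in several crosses of those strains, but they were weak or, near Hlx, at the edge of the window. The comparison therefore does not show that hotspots of CAST persist in crosses more than those of B6 or 13R. A hotspot within 10000 bp of Psmb9, an immunoproteasome gene of the major histocompatibility complex, was present in 8 lists. In CAST it lay at chromosome 17 (34178205 to 34182228) with rank 261 of 15068, and its crosses included B6fXCASTm at rank 787 and PWDfXCASTm at rank 475. Those of 13R (rank 14733 of 14752, near the floor of the list) and MOLfX13Rm lay elsewhere in the window, and the other crosses with 13R had none. Near Hlx, a homeobox gene on chromosome 1, 9 lists had a hotspot, with CAST at rank 2033 (184721776 to 184724225). The one in B6 lay elsewhere (184742412 to 184745003, rank 4072), with its centre outside the window. No cross with B6 had it counted in the window, but a narrower call at the same centre would not be counted. Whether crosses with B6 carry it was therefore not settled. H2-Eb1 had one in 13 lists, with CAST at rank 7495, and the one in B6 (rank 14147) was absent from the crosses of B6 with 13R, MOL and CAST, the last holding one at the CAST place. Esrrg, a long gene on chromosome 1, had at least 1 hotspot in all 26 lists, the knockout included, with C3H at rank 86 of 14645 (187615193 to 187621836).

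Shorter autosomes tended to carry more hotspots per Mb, but the relation passed by Pearson's r in 3 of 7 lists and weakened without the chromosomes of extreme length. Pearson's r between density and length over 19 autosomes was -0.660 in MOL (permutation p = 0.00212, adjusted over 7 lists 0.0134; rho = -0.621, permutation p = 0.00567, adjusted 0.0259). It was -0.610 in C3H (permutation p = 0.00542, adjusted 0.0134; rho = -0.600, p = 0.00741, adjusted 0.0259) and -0.604 in the knockout (permutation p = 0.00576, adjusted 0.0134; rho = -0.495, p = 0.0330, adjusted 0.0699). Without the 2 autosomes farthest from the median length, r was -0.521 in MOL, -0.356 in C3H and -0.375 in the knockout. The other 4 lists did not pass, with r between -0.421 in B6 and -0.185 in 13R, and without those 2 autosomes r was 0.416 in PWD and 0.150 in 13R. By summed strength per Mb, C3H no longer passed (r = -0.400, permutation p = 0.0905, adjusted 0.158), PWD did (r = -0.551, permutation p = 0.0148, adjusted 0.0345; rho = -0.247, adjusted 0.356), and r in PWD was 0.0354 without those 2 autosomes.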

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

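The tests in this part were chosen after the results were seen, except those on knockout strengths and on Y hotspots in equal numbers of hotspots, whose outcome was not known when they were chosen. In 17 groups of lists the most extreme list was compared with the others, and chance alone picks out about 1 in 20 groups.

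PWDfXB6m had a knockout-site share of 5.93%, far from the other crosses with a PWD parent, the next being 2.40%. Chance overlap is excluded, since the highest of 100 shifted knockout lists gave 1.20%, and list length alone is excluded, since the 3 lists at least as long reached at most 1.61% (C3HfXB6m). List depth still matters to the size: among the strongest 10445 hotspots, the length of the shortest list, the share fell to 1.55%, against 0.604% to 1.10% in the other 24 lists. Over the 692 sites shared with the knockout alone, strengths did not follow those of the knockout (rho = -0.0529), which was chosen beforehand as evidence against such reads, but these sites lie at the floor of the list, with a median strength percentile of 9.57, so knockout reads and use of PRDM9-independent sites in this hybrid cannot be told apart. With knockout sites at a hotspot of either parent left out, the share found in this library was 19.8% among the strongest 10% of knockout sites. In the next 10% it was 2.29%. In B6fXPWDm (1.95%), PWDfXC3Hm (3.94%) and PWDfXMOLm (4.50%) the share was raised in the strongest 10% alone, and both accounts predict such a gradient.

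Lists with a MOL father had more Y hotspots than all other lists except B6, which had 152 holding 0.223% of its strength: 80 in B6fXMOLm, 104 in C3HfXMOLm, 100 in CASTfXMOLm, 96 in PWDfXMOLm and 127 in MOL, a signal on a chromosome that the comparisons do not use; PWDfXMOLm, with 96, also stood far from the other PWD crosses. One place, at Y 4150841 to 4152176 in B6fXMOLm, held 83.3% of Y strength there. Lists with a MOL mother and another father had 12 Y hotspots each, so the count followed the father in the MOL crosses. A MOL Y chromosome that differs from the reference may be the source, but breaks on that chromosome would give the same values and were not tested apart. A high count also arose without a MOL Y, in inbred B6 with 152, while crosses with a B6 father had from 1 (PWDfXB6m) to 13 (13RfXB6m). Longer lists reaching weaker hotspots were also weighed. B6fXMOLm had 80 Y hotspots in a list of 12610, while PWDfXCASTm (19084), C3HfXB6m (18155) and the knockout (30929) had 8, 12 and 4. These values argue against list length as the source for the MOL-father lists, although B6, with 152, was also long (19528). In the test chosen beforehand, among the strongest 10445 hotspots, the MOL-father lists held 13 to 30 Y hotspots and the other lists 1 to 16. PWD, at 16, overlapped, so that test alone did not decide.

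The X share of strength was low in crosses with a CAST, MOL or PWD parent (7.80% ± 1.89, SD, n = 14) but not in the crosses among B6, C3H and 13R (11.8% ± 1.5004, n = 5); MOLfX13Rm (12.3%) and PWDfX13Rm (10.4%), with a 13R parent, were not low. Loss of reads from a diverged X in mapping is excluded for the 3 crosses with a B6 mother, whose X is the reference X: they reached at most 6.78% (B6fXMOLm), against 12.4% in inbred B6. Other crosses were set beside that of the same mother, and so the same X, with a 13R father. Lower by more than 2 SD of the crosses among B6, C3H and 13R were C3HfXCASTm (by 6.78 percentage points), C3HfXMOLm (4.45), MOLfXB6m (3.25), PWDfXB6m (4.72) and PWDfXCASTm (3.32). These values argue against loss in mapping as the whole cause there but do not exclude it. Each comparison sets 1 library against 1, and the SD is a spread between genotypes, chosen after the values were seen. Loss in mapping stays open for PWDfXC3Hm (2.10) and PWDfXMOLm (2.46). It also stays open for the crosses with a CAST mother, which have no such cross and of which CASTfXB6m lay 0.899 above B6fXCASTm. A candidate explanation is more signal at autosomal hotspots in neither parent: over the 14 crosses the X share fell as the share in neither parent rose (r = -0.619, permutation p = 0.0178, adjusted over 2 sets 0.0356; rho = -0.534, permutation p = 0.0517, adjusted 0.103). Without the 2 crosses farthest from the median r was -0.413, and without the crosses with 13R it was -0.455 (n = 12, permutation p = 0.137; rho = -0.322, permutation p = 0.308), so the relation rests on a few crosses and cannot be told apart from a difference between them.

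B6 had 19528 hotspots, far from the other 5 inbred strains, of which the next had 15768.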

How the results depend on the processing

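The alternatives were planned before the data were examined, except leaving out lists and comparing equal list lengths. No paired analysis was possible because each genotype has 1 library, apart from the tests within crosses and within reciprocal pairs, which are paired by design. The median sharing of inbred pairs (0.833%) was 3.82% with any overlap, 1.98% with centres under 1000 bp apart, 1.29% with reciprocal overlap of 50%, 0.475% in the strongest 50% and 0.328% in the strongest 5000; the shifted lists also rose, to 2.77%, 1.23% and 0.863% under the first 3, so wider rules add chance matches. The named pairs moved as well, B6 and C3H from 33.3% to between 17.0% (strongest 5000) and 36.1% (any overlap), MOL and PWD from 13.0% to between 6.58% and 15.7%, CAST and PWD from 11.9% to between 7.87% and 14.2%, and CAST and MOL from 2.66% to between 1.08% and 5.55%, under the same settings. The median share in neither parent (20.7%) was 17.4%, 18.9%, 30.4%, 29.4% and 37.1% under those settings in that order, and 22.9% by strength; shorter parental lists leave more hotspots unmatched by construction. The PWD contrast of knockout-site shares (1.37) kept its direction and its side of the threshold under 5 alternatives but shrank to 0.457 with reciprocal overlap of 50% and 0.386 by strength among these (1.90 with any overlap, 1.78 with centres under 1000 bp apart, 1.36 in the strongest 50% of knockout hotspots), and lost it in the strongest 50% (0.0684), the strongest 5000 (0.000912) and without both B6 and PWD crosses (0.516); leaving out each cross gave 0.649 (without PWDfXB6m) to 1.71. Gene lists that passed fell from 5 to 3 with a window of 2500 bp and numbered 6 with the strongest 50% of knockout hotspots. The list added there was that of Sertoli cell genes, which had fewer (by 26.1 percentage points, Fisher's exact test, adjusted p = 0.0235). The autosomal difference by cross direction (-0.0971) turned to 1.79 with reciprocal overlap of 50%, 0.399 in the strongest 50% and 1.30 in the strongest 5000. The strength of hotspots in neither parent (-3.57) became -18.0 with reciprocal overlap of 50%. It shrank to -2.45 with any overlap, -1.68 with centres under 1000 bp apart, -0.876 in the strongest 50% and -1.93 in the strongest 5000, and did not pass under these. Hotspots at known loci, 56 gene and list pairs, fell to 36 within the gene bodies alone. Where no construction is named, the cause was not tested. By strength, the autosome density relation passed by Pearson's r in 3 lists as before, with PWD in place of C3H. By rho only MOL of these passed (adjusted permutation p = 0.0157), with 0.141 in the knockout and 0.356 in PWD. The X difference of inbred and F1 lists passed by strength (2.98) and in the strongest 5000 (1.66) and without any 1 list (0.909 to 1.24); removing the pseudoautosomal region tested nothing, since no list has a hotspot there. Reciprocal crosses and gene ends kept direction and call under all 5 and 3 alternatives. The motif alternatives were not run. Unknown read depth limits every comparison of list lengths and weak hotspots.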

Other observations

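The tests in this part were chosen after the results were seen. Hotspots on X lay at knockout sites far more often than autosomal hotspots did in many lists. Whether this reflects more breaks at such sites on X, rather than how readily weak hotspots are called there, was not tested. In B6, 17.6% of X hotspots (15.5 to 19.8, 219 of 1246) lay at knockout sites against 1.58% on the autosomes, and in PWDfXB6m 21.2% against 5.93%. In the 13 lists with no 13R or CAST genome the X share ran from 7.22% (B6fXC3Hm) to 21.2%, and all 13 exceeded their 100 shifted lists, where the highest was 1.42%, so chance overlap is excluded there. In the 12 lists with a 13R or CAST genome it ran from 0.567% (C3HfXCASTm) to 3.80% (C3HfX13Rm), and 7 exceeded all shifts; inbred 13R had 0.675% and inbred CAST 0.774%.

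On the autosomes the same division held. The 10 crosses with a 13R or CAST parent had knockout-site shares between 0.633% and 0.869%, below the mean of their shifted lists in all 10, and the 9 others between 1.09% and 5.93%. The hypothesis that a 13R or CAST parent goes with a lower share was tested with a correction for the choice among 15 pairs of strains: the difference of means was -1.34 percentage points (permutation p = 0.0888), and on ranks the permutation p was 7.3e-04. The tests differ in outcome, and crosses share parents, so the question stays open. 13R and CAST may leave fewer breaks for such sites, as they also supplied the larger part of hotspots in their crosses. MOL, however, also supplied the larger part against B6 (63.3% and 64.5%), C3H (60.9%) and PWD (58.6%). At knockout sites B6fXMOLm had 1.14% and C3HfXMOLm 1.11%, within the range of their shifted lists (highest 1.22% and 1.30%). MOLfXB6m had 1.32% and PWDfXMOLm 2.40%, above theirs (1.19% and 1.21%). These MOL crosses did not fall below the mean of their shifted lists, as those with 13R or CAST did. PWDfXMOLm also has a PWD parent, so whether a larger part goes with a low share was not settled for MOL.

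Hotspots in neither parent recurred in other crosses of the same strain. In all 19 crosses the averages over other crosses of the mother's and of the father's strain exceeded that over unrelated crosses, which ran from 0.885% (C3HfXB6m) to 14.7% (PWDfXC3Hm). Presence in the reciprocal cross ran from 42.8% (C3HfXB6m), 43.0% (13RfXB6m) and 64.7% (B6fX13Rm) to 96.5% (B6fXPWDm). Of the 3838 in B6fXPWDm, 96.5% were present in the reciprocal cross, 39.8% on average in other crosses with PWD, 19.997% in other crosses with B6 and 13.1% in crosses with neither strain. In C3HfXCASTm the averages were 52.1% in crosses with CAST, 16.04% with C3H and 10.5% in unrelated crosses.

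The place on chromosome 14 near Gm2244 had a strength of 7852 in B6fXCASTm, 6592 in CASTfXB6m and 477 in MOLfXB6m, and no hotspot in the other 23 lists. Those lists include C3HfXCASTm, CASTfXMOLm and PWDfXCASTm, which also have a CAST parent. The raw scores are not comparable between lists, and whether the signal reflects breaks was not tested.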
